A study of Nicotiana tabacum with 10 samples.

How the data were processed

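RNA sequencing was performed on suspension cultures of BY-2, a fast-dividing tobacco (Nicotiana tabacum cv. Bright Yellow 2) cell line that needs an external auxin in its medium. Per the labels, 7 control samples came from cells grown with the synthetic auxin 2,4-dichlorophenoxyacetic acid at 0.2 mg/l, and 3 auxin-free samples from cells inoculated into the same medium without it. All were collected 48 h after inoculation. Groups and replicate numbers were taken from the sample titles. The series' design text calls the control samples biological replicates and lists the auxin-free ones as replicates. No label says whether the auxin-free samples came from separate cultures, so p-values measure the spread between these samples.

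The reads were trimmed with Trimmomatic and quantified with Salmon, per the submitters' processing notes; their versions, options and the index are not given in the sources used here. Each deposited file gives, per the file headers, the estimated count of reads, the TPM value (transcript abundance scaled to a common sum and by effective length), the length and the effective length (unit: bases) of 69500 gene models, with 1 model per gene. The estimated counts deposited by the authors are not normalized and need not be whole, because Salmon divides reads that match several models among them. Tobacco is an allotetraploid, so many models have a near-identical partner from the other parental genome, and a read total of 1 model can depend on that division. Of the models with reads, 22.3 to 24.1% per library had a whole count, within a tolerance of 0.001. Model lengths were multiples of 3 for 83.7% of models, so for most of them the length is a coding length. Where the text speaks of length, it means the length of the model in the deposited files.

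The models carry Nitab4.5 identifiers, and 0 of the 69500 matched the reference table of tobacco gene names used here, which lists 79372 genes of another assembly. No gene names, functions or pathways were therefore assigned. The gene lists fixed before the data were examined, for auxin oxidation, conjugation, transport and response, cell division, starch, nicotine and other functions, were not run for that reason. The rule fixed for this case names by identifier only the first 2 models up and the first 2 down, ranked by absolute log2 fold change among models with adjusted p at most 0.05, a mean of at least 10 CPM in the higher group and no overlap between the groups. The part of an identifier before the letter g was read as the scaffold and the number after it as the order of models along it.

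Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with its default minimum count of 10, TMM scaling, robust quasi-likelihood fits and quasi-likelihood F-tests of auxin-free against control over all 10 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values in the text are counts relative to library size with TMM scaling, unless given as a percent of reads. The alternatives, listed before the data were examined, were DESeq2 1.42.0, limma-voom and limma-trend on log2(TPM + 1) with limma 3.58.1, DESeq2 size factors, upper-quartile scaling, no filter, a filter of at least 1 CPM in 3 samples, offsets from the deposited effective lengths, the replicate number as a block, the 2 sets of controls that differ in the serial numbers of their files, a test against a 1.5-fold change, and leaving out each library in turn. Removal of the trend on length, restriction to whole-count models, the counts of models present in 1 group, and all work on neighbouring models except the same-direction share were added after seeing the data. A fold against a group with no reads was computed against 3 counts over that whole group and is a lower bound. Intervals and bounds of this kind cover counting error only. Single values per library were compared with exact two-sided permutation tests over the 120 splits of 10 libraries into 7 and 3, whose smallest possible p is 0.00833.

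Before use, the tests were tested on simulated data drawn for 37034 models from the control means, dispersions and library sizes, with 50 models changed at each of 4 fold sizes in the 3 auxin-free libraries. For this comparison edgeR recovered 8% of 50 models changed 1.5-fold, 40% of 50 changed 2-fold, 98% of 50 changed 4-fold and 100% of 50 changed 8-fold, with 10 false calls. With so few models changed, the adjusted threshold is stricter than in the real comparison, where the calls reach a raw p of 0.0316. At that raw p the simulation recovered 52% of 50 models changed 1.5-fold, 88% of 50 changed 2-fold and 100% of 50 changed 4-fold. The changed models were drawn only from those above a set mean count, so these rates do not cover models near the filter's minimum. Nor was the scaling tested under a shift as wide as the real one. Library totals ran from 11280031 to 23705016 estimated reads. Every pair of libraries of a group differed by more than sampling noise (chi-square per degree of freedom of 3.79 to 61.5), so none was counted as a duplicate. Both groups carry the replicate numbers 1 to 3, and the check of whether these pair the libraries is described with the effect of the processing.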

Results

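The transcriptome of BY-2 tobacco cells was compared between 7 samples supplied with 2,4-dichlorophenoxyacetic acid, a synthetic auxin, and 3 samples deprived of it, 48 h after inoculation. Auxin is the plant hormone that sustains division of these cells in culture. The series' title concerns DAO1, a dioxygenase that oxidises auxin, and its action on auxin-amino acid conjugates. The level of DAO1 was not analysed here, because the identifiers of the deposited files were not paired with gene names. The control libraries held 16603789 ± 4781132 estimated reads (SD, n = 7; range 11280031 to 23705016), and the auxin-free libraries 15859243 ± 605700 (SD, n = 3; range 15159895 to 16216471). Of the 69500 gene models, 13083 had no reads in any library and 37034 were abundant enough to test.

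The auxin-free samples had a transcript profile far from that of the controls. The mean Spearman correlation of log2 CPM was 0.735 ± 0.0346 (SD, 21 pairs) between groups, against 0.968 ± 0.0163 (SD, 21 pairs) among controls and 0.965 ± 0.0143 (SD, 3 pairs) among auxin-free libraries. The highest correlation between groups, 0.791, lay below the lowest within a group, 0.931. These pairs share libraries and are not independent. The first principal component held 80.1% of the variance and placed the 3 auxin-free libraries between 228 and 271 and the 7 controls between -128 and -66.7. The second component held 7.41% and separated the controls from one another, with control replicates 3, 6 and 7 between -78.1 and -47.9 and control replicates 1, 2, 4 and 5 between 22.3 and 85.7. Control replicate 7 had the highest mean correlation with the auxin-free libraries, 0.772, and control replicate 5 the lowest, 0.701.

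**Figure D1:**
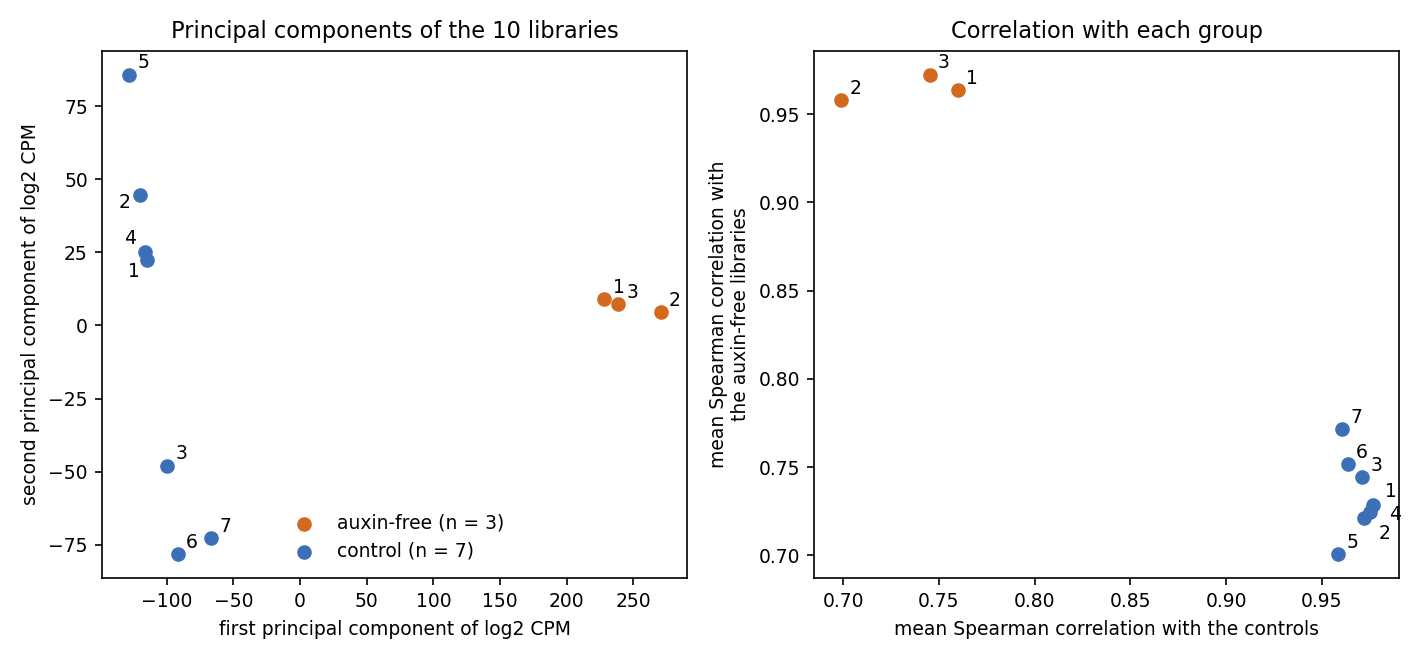
Left, principal components of log2 CPM of the 37034 tested gene models for 7 control (blue) and 3 auxin-free (orange) libraries, numbered by replicate, in arbitrary units. Right, each library's mean Spearman correlation with the other controls (horizontal axis) and with the other auxin-free libraries (vertical axis); the groups stand apart on both, and control replicate 7 is the control nearest to the auxin-free group, at 0.772.

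Most of the tested transcriptome differed between the groups. Of 37034 gene models, 23434 (63.3%) differed at an adjusted p of 0.05 in edgeR's quasi-likelihood test, 12194 of them higher and 11240 lower in the auxin-free samples. At least a 2-fold difference was reached by 8565 models that rose and 7464 that fell. The groups did not overlap in 10704 of the models that rose and 9355 of those that fell. Among all tested models 20439 showed no overlap, where chance gives 1.67% of models for 7 libraries against 3. The higher number of rising models was not independent of the scaling: upper-quartile scaling gave 10540 up and 13202 down. It moved the median log2 fold change of all tested models from 0.0237 to -0.158. With the main scaling, the excess of rises was absent among the 2445 tested models with whole counts in every library. Of these 649 rose and 736 fell, against 11545 and 10504 of the rest. Against control replicates 6 and 7 alone, whose files carry serial numbers next to those of the auxin-free libraries, 18983 models differed. Against control replicates 1 to 5 alone 24323 differed. The sets differ in size and so in power, and the counts do not measure how near each set lies to the auxin-free group.

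Which direction held more of the 2-fold differences depended on the scaling: upper-quartile scaling gave 7425 models up and 9003 down, against the 8565 and 7464 above. The largest differences were more often increases. A difference of 16-fold or more was found for 1807 models that rose and 802 that fell, where the 127 rising and 161 falling models with no reads in one group were counted at the lower bound set by 3 reads in that group. On fitted folds without that bound, 1807 rose and 879 fell at least 16-fold, and with upper-quartile scaling 1676 rose and 959 fell. Between 8- and 16-fold there were 899 rising and 591 falling models. Between 2- and 4-fold the order was the other way, with 4148 rising and 4501 falling. Of the 13600 models that did not pass the test, 2806 had a 95% interval of the fold within 1.5-fold in either direction, so for the remainder a moderate change was not excluded.

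**Figure D2:**
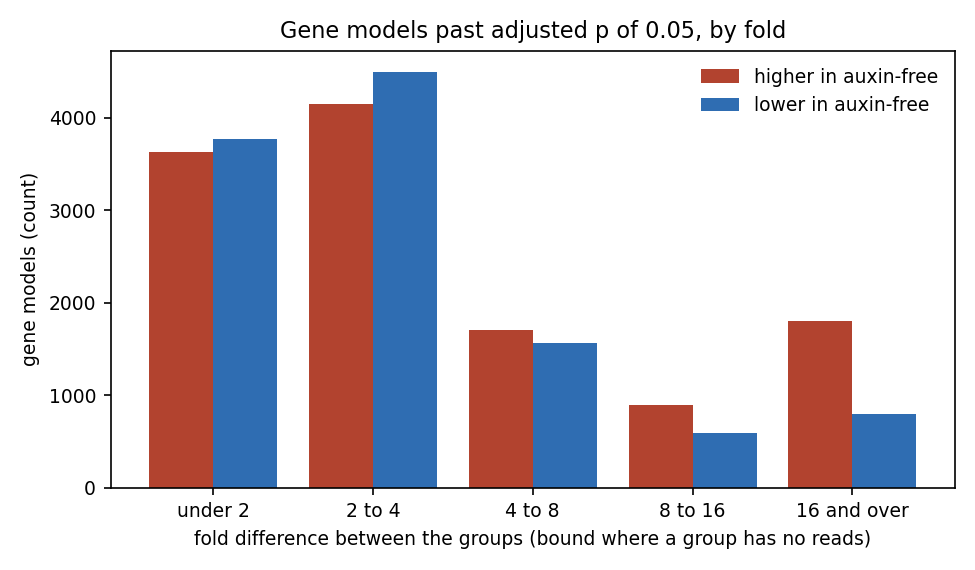
Number of gene models past an adjusted p of 0.05 (vertical axis) by size of the fold difference between auxin-free and control samples (horizontal axis), with models higher in auxin-free samples in red and lower in blue. In the band of 16-fold and over, 1807 models rose and 802 fell.

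The models that changed carried most of the reads in both states. The 12194 rising models took 17.1% ± 2.1 of the reads in control libraries (SD, n = 7) and 54.4% ± 3.48 in auxin-free libraries (SD, n = 3). The 11240 falling models took 57.9% ± 3.97 in controls and 21.3% ± 3.12 in auxin-free libraries. These sets were chosen on the same libraries, so the sums describe the size of the shift and are not a further test of it. The 1807 models that rose at least 16-fold went from 0.431% ± 0.152 to 15.3% ± 1.52 of reads.

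Abundant transcripts of the controls mostly fell. Of the 1000 most abundant models in control libraries, 738 fell, 87 rose and 175 did not pass the test, and 593 of those that fell did so at least 2-fold. Of the 1000 most abundant in auxin-free libraries, 577 rose, 201 fell and 222 did not pass. Both lists are chosen by the level in one group, which by itself favours a fall in the first and a rise in the second. The lists shared 456 models, against 27 for independent lists. Among the 10 most abundant models of the auxin-free samples 9 rose, with fitted log2 fold changes of the 10 between -0.733 and 11.8. Among the 10 most abundant of the controls 9 fell, with log2 fold changes of the 10 between -2.37 and 0.141.

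The auxin-free transcriptome was also more concentrated in few models. The 10 most abundant models of each library took 7.5% ± 0.0666 of reads in auxin-free libraries (SD, n = 3) and 3.1% ± 0.424 in controls (SD, n = 7). Every auxin-free library lay above every control (exact two-sided permutation p = 0.00833, the smallest the design allows; 0.0222 after Benjamini-Hochberg adjustment over 8 library measures). The 100 most abundant models took 17.4% ± 0.737 and 11.9% ± 0.879 respectively, with the same p (exact permutation p = 0.00833, adjusted 0.0222). The number of models at 1 CPM or more differed less, 32070 ± 219 in auxin-free and 31130 ± 417 in control libraries (exact permutation p = 0.0167, adjusted 0.0334).

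A small set of models was present in one state and near absent in the other. With at least 10 CPM in every library of one group and at most 3 reads in every library of the other, 71 models were present in the auxin-free samples alone and 34 in the controls alone. All 71 and all 34 passed the test, but they were chosen on the same counts, so this is no further support. The 71 had a median of 33 CPM and together took 0.352% ± 0.0309 of auxin-free reads. Of them, 18 had no reads in any control, and 4 of the 34 had none in any auxin-free library. Without control replicate 7 the 71 became 95, and without auxin-free replicate 3 the 34 became 52.

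The 4 models named by the fixed rule all belonged to this class. Nitab4.5_0002196g0060.1, a model of 987 bases, had no reads in the 7 controls and 126 ± 40.7 CPM in the auxin-free libraries (SD, n = 3), at least 4879-fold higher (edgeR adjusted p = 1.86e-07). Nitab4.5_0001225g0250.1, of 1602 bases, likewise had no control reads and 118 ± 124 CPM in the auxin-free libraries, at least 4657-fold higher (edgeR adjusted p = 4.25e-05). Its 3 auxin-free values ran from 24.3 to 259 CPM, so its level was poorly fixed, and without auxin-free replicate 2 the bound falls to at least 1884-fold higher. Nitab4.5_0003159g0030.1, of 546 bases, had 114 ± 31 CPM in the controls (SD, n = 7) and no reads in the auxin-free libraries, at least 1792-fold lower (edgeR adjusted p = 2.21e-08). Nitab4.5_0001439g0060.1, of 1830 bases, had 25.2 ± 10.6 CPM in the controls and none in the auxin-free libraries, at least 379-fold lower (edgeR adjusted p = 8.79e-07). Only Nitab4.5_0002196g0060.1 had whole counts in every library. The levels of the other 3 include reads that Salmon divided with similar models, and their absence in one group can depend on that division.

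**Figure D3:**
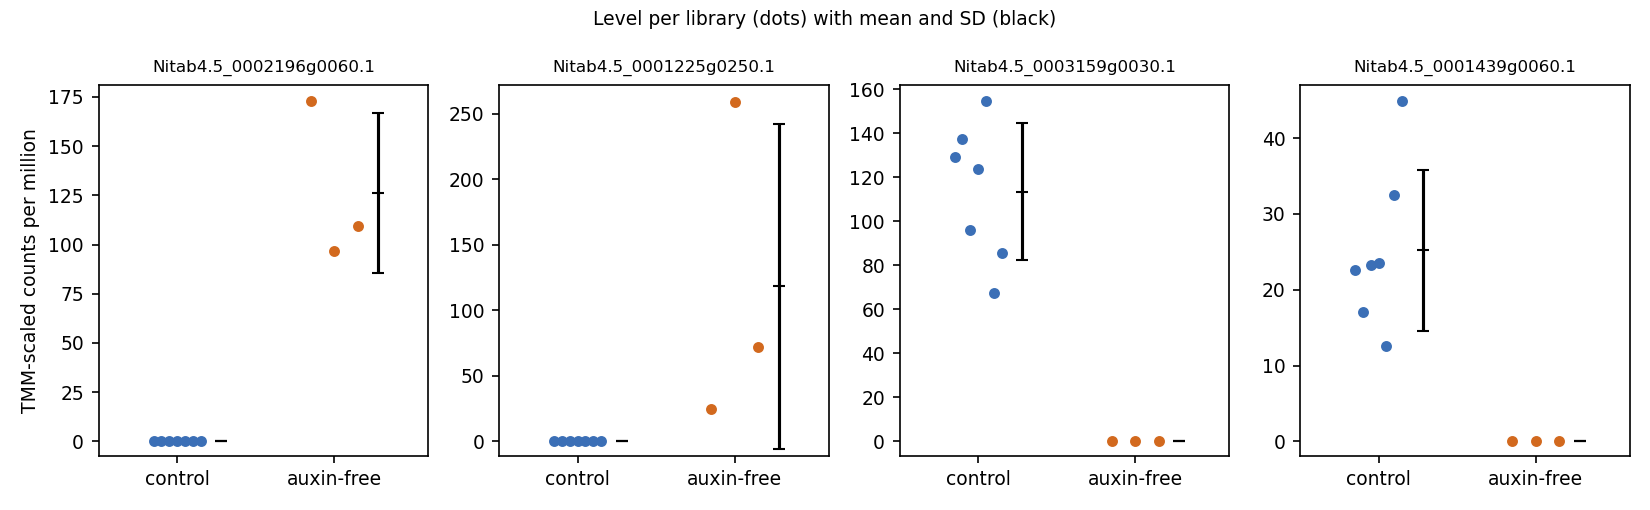
Level of the 4 gene models named by the fixed rule in each library (dots), in TMM-scaled CPM (vertical axis, linear, a separate scale per panel), with mean and SD in black, for 7 control and 3 auxin-free samples. Nitab4.5_0002196g0060.1 and Nitab4.5_0001225g0250.1 have reads only in the auxin-free libraries, and Nitab4.5_0003159g0030.1 and Nitab4.5_0001439g0060.1 only in the controls.

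Short models fell more often and long models rose more often. In the shortest of 8 length bins, 122 to 537 bases, 968 models rose and 1727 fell, with a median log2 fold change of -0.427 over 4670 models (SD 2.41). In the longest, 2340 to 13563 bases, 2033 rose and 788 fell, with a median of 0.45 over 4630 models (SD 1.66). The median rose from bin to bin through all 8. The libraries of the groups also differed in the gap between a model's length and its effective length, which Salmon estimates for each library. This gap is not a measure of fragment length alone: among models with reads, 97.4 to 98.2% of the lengths shared by several models had differing effective lengths (tolerance 0.001 bases), and the effective length exceeded the length in 6.77 to 9% of models in controls and 14.5 to 16.8% in auxin-free libraries. The median gap over models longer than 1400 bases was 380 ± 17.5 bases in controls (SD, n = 7; range 356 to 401) and 269 ± 11.6 in auxin-free libraries (SD, n = 3; range 256 to 276), with no overlap (exact two-sided permutation p = 0.00833, adjusted 0.0222). Among the controls this gap fell at every step in replicate number, from 401 bases in control replicate 1 to 356 in control replicate 7. The serial numbers of the files run in the same order. Over models with reads the median gap fell from 358.5 bases in control replicate 1 to 315.1 in control replicate 6, but was 322.8 in control replicate 7. With each library's trend on length removed, 24031 models differed, and 21371 of the 23434 calls were kept with the same direction.

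**Figure D4:**
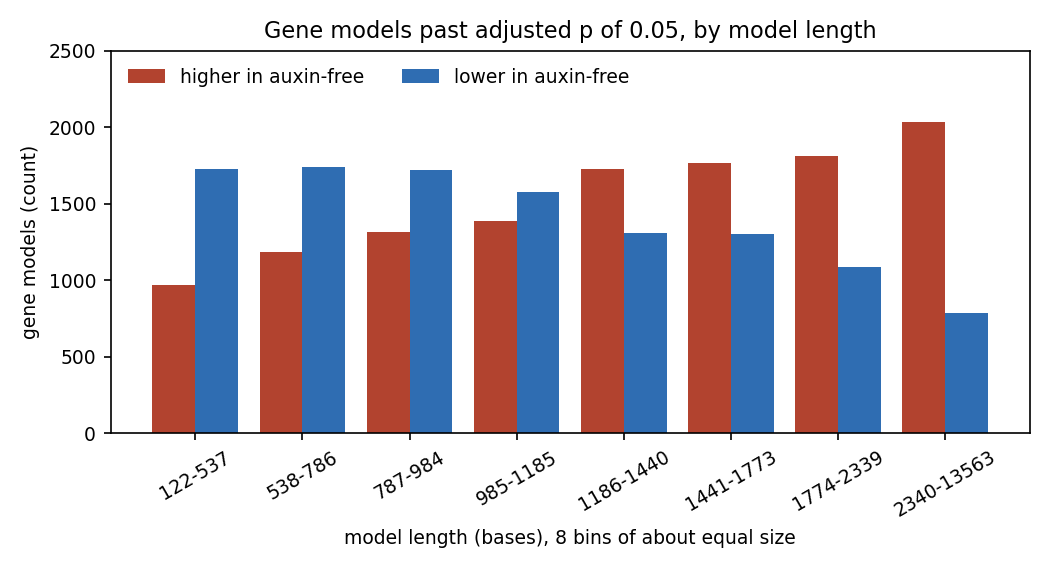
Number of gene models past an adjusted p of 0.05 that were higher (red) or lower (blue) in auxin-free samples (vertical axis), in 8 bins of model length in bases (horizontal axis). Falling models outnumber rising ones in the shortest bin, 1727 against 968, and rising ones in the longest, 2033 against 788.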

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

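The tests of serial numbers and of control replicate 7, and the reading of the length trend over the 3 lower abundance groups, were chosen after the results were seen. Removal of the trend on length and the use of whole counts were chosen after the data were seen but before their own results.

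Control replicate 7 had the highest level among the controls in the models specific to auxin-free samples. In each control, models with at least 20 CPM in every auxin-free library and a median over the other 6 controls of at most 0.5% of the auxin-free level were examined. Their median level in control replicate 7 was 0.476% of the auxin-free level over 119 models, against 0.054 to 0.125% in the other controls. The gap to the nearest control was 0.832 of the whole range, above Dixon's critical value of 0.568 for 7 samples. It was the only flag among 14 measures tested, where chance flags about 5% of such sets, so 1 flag is within what chance can give. The displacement described next and the mean correlation with the auxin-free libraries were also tested and were not flagged.

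The same library was displaced toward the auxin-free profile by 11.8% of the whole change over all tested models, with 3 of the other controls as its baseline and the remaining 3 as that of the change (range over the 20 such divisions 10.1 to 12.5), while the other controls lay between -5.81 and 4.48%. That displacement was computed on log2 CPM, whereas the share of the auxin-free-specific models was computed on CPM. Carry-over of 11.8% of auxin-free RNA or reads would lift those models to a similar share. Their median of 0.476%, with an upper bound of 1.03% for the middle 50% of models, lies far below it. A lower share can displace a profile on the log scale by more than itself, so the comparison argues only against carry-over of that size. Carry-over at a lower share stays open for the displacement and for the raised models. Their reads varied around a common share with a chi-square per degree of freedom of 22.6 for the best-matching source library, above the 5 first set as the bound against it. That bound allowed for counting noise alone, and was set aside once the value was known, because auxin-free libraries thinned by simulation to that depth gave 3.4 to 9.27 around the mean of the other libraries of their group. The 22.6 lies above these as well, but 3 libraries do not bound how far another auxin-free source could differ. Shorter fragments stay open for the displacement. The length gap used for them is not a measure of fragments alone, since effective lengths differed between models of equal length. Over the 7 controls the displacement and the length gap had a Spearman correlation of -0.464 (exact permutation p = 0.302, adjusted 0.354) and a Pearson correlation of -0.709 (exact permutation p = 0.0724, adjusted 0.29; -0.471 without the 2 libraries farthest from the median gap). A culture further along the path that auxin-free cells take is a biological candidate explanation that no label tests.

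Of 100 splits of the 10 libraries into 7 and 3, only 1, the real split, reached the 23434 changed models. The highest other split gave 4. Every other split puts libraries of both groups into at least 1 set and so widens the spread there. Its low count thus follows from the distance between the groups. The splits also treat the libraries as independent, and no label says that the auxin-free samples came from separate cultures. A chance difference between cultures is therefore not excluded. A difference in fragment length does not account for the number of changed models through a trend on length. With that trend removed, 24031 models were called. The 2445 tested models with whole counts in every library were called 0.889 times as often as the rest, 56.6% against 63.7%. Reads shared between similar models were thus not needed for a high share of calls. The 2 sets were not matched in abundance or length. Whether 1 change was counted in each of 2 similar models was not tested, and that could raise the number. A batch in serial-number order could begin at control replicate 6. If it made the whole change, control replicates 6 and 7 would lie near the auxin-free libraries. Their displacement was 10.8% of the change (9.11 to 11.6 over 10 divisions of the other controls), which argues against such a batch. A batch that made a part of the change is not excluded by this value. Nor does the value test a batch that begins earlier, which would include controls of the baseline. A batch that begins with the auxin-free libraries also follows the serial numbers, and it cannot be told apart from the group. The length gap of the controls over models longer than 1400 bases fell in the order of those numbers, toward that of the auxin-free libraries. Over models with reads, control replicate 7 broke that order. A drift in that order stays open for the gap. With offsets from the effective lengths 23471 models were called. No label names a batch of preparation or sequencing, so only the order of the serial numbers was examined. The division of control replicates 3, 6 and 7 from 1, 2, 4 and 5 on the second principal component was not examined as a batch. The withdrawal of auxin named by the design stays open.

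The trend on length was not confined to abundant transcripts, and whether it comes from the fragments was not decided. The auxin-free libraries gained 0.241 ± 0.0094 log2 units per doubling of length (SD, n = 3) over the control mean, and single controls ran from -0.224 to 0.195. Control replicates 3, 6 and 7, which lay together on the second principal component, had slopes of 0.139, 0.195 and 0.163. Control replicates 1, 2, 4 and 5 ran from -0.224 to -0.0782. Differences in slope of this kind thus also occurred between controls that were all supplied with auxin. The line through the 7 controls predicted 0.524 at the auxin-free length gap (0.327 to 0.717 when 1 control was left out), but that gap does not measure fragments alone and the relation among controls was weak (Pearson r = -0.506, exact permutation p = 0.24, adjusted 0.354; Spearman rho = -0.429, exact permutation p = 0.354, adjusted 0.354; r = -0.307 without the 2 farthest libraries). Models were divided into 4 equal groups by length and into 4 by mean abundance. The median log2 fold change of the longest group lay above that of the shortest by 0.857 (95% bootstrap interval over models 0.705 to 1.07) among the least abundant models, by 0.683 (0.592 to 0.775) and 0.888 (0.802 to 0.974) in the groups between, and by 1.32 (1.23 to 1.42) among the most abundant. Relative to the most abundant group these were 0.649 (0.519 to 0.816), 0.517 (0.436 to 0.603) and 0.673 (0.59 to 0.756). Short abundant transcripts that fell together were predicted to leave the least abundant group under 0.25 of the difference in the most abundant. The observed 0.649 lay above that but below the 0.75 first set as the value against them, so that rule did not decide. The 3 lower groups still held a difference of their own, so short abundant transcripts do not account for the whole trend. The short models had medians of -0.00453, -0.305, -0.515 and -1.11 from the least to the most abundant group, and the long models 0.853, 0.378, 0.373 and 0.212, so the trend among the least abundant models was a rise of long models. That short abundant transcripts add to the larger difference in the most abundant group was not tested apart. The fragments stay open, as does an action of auxin withdrawal that differs with length, which was not tested.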

How the results depend on the processing

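The restriction to whole counts, removal of the length trend, the presence counts with their repeats, and repeats of the neighbour share were chosen after the data were seen. The number of changed models stayed within 1.5 times the reported 23434 under 12 other settings (18983 to 25491) and without each library in turn (21106 to 23712). So did the 16029 changed at least 2-fold, at 12256 to 18878 and, without each library in turn, 15179 to 16565; a test against a 1.5-fold change called 16316. Restricting the fit to models with whole counts left 2459 to test, and by that construction 1379 changed and 1133 changed at least 2-fold. DESeq2 called 24017 models and shared 23320 of the reported calls in the same direction. Models present in auxin-free samples alone numbered 71 to 95 without each library in turn, and those present in controls alone 34 to 52, the highest without auxin-free replicate 3. All 89 alternative fits of the 4 named models kept direction and call, with a highest adjusted p of 0.019. The mean correlation between groups kept to within its spread under the stricter filter. Neighbouring changed models shared direction in 53.65% of pairs without control replicate 7, and the share lost its significance among whole-count models, at 52.81%, and among whole-count pairs of differing length, at 52.78%, which left 89 and 72 pairs. With the replicate block, 20978 models changed, 16030 of them at least 2-fold. Same-numbered libraries correlated in their deviations at 0.0702, -0.0979 and -0.0258, and not every library correlated best with its own number. The numbers thus gave no sign of pairing the samples, though so few pairs cannot exclude it. The gene list tests were not run, since no model could be paired with a name.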

Other observations

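The run tests, the tests on the scaffold of abundant models and the restricted neighbour tests were chosen after the data were seen; the same-direction share of neighbours was planned. Of the 10 most abundant models in the auxin-free samples, 4 lay on 1 scaffold, Nitab4.5_0000032, within a stretch of 7 consecutive models. In 10000 random draws of 10 tested models, no more than 2 ever shared a scaffold. The 4 models, of 714 to 888 bases, together rose from 0.191% ± 0.0791 of reads in controls (SD, n = 7; at most 0.349%) to 2.93% ± 0.172 in auxin-free libraries (SD, n = 3; at least 2.78%). Their log2 fold changes were 3.11 to 11.8 (edgeR adjusted p at most 6.02e-07). Of the other tested models in the stretch 2 fell, and on the rest of the scaffold 5 rose and 7 fell among 19 tested. None of the 4 had whole counts in every library, so each level includes reads that Salmon divided with similar models.

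Runs of at least 4 consecutive models that all fell at least 2-fold numbered 21, against a mean of 8.88 and a maximum of 20 in 500 permutations of the tested models (permutation p = 0.002, the smallest these permutations can give). Runs that rose numbered 20, against a mean of 14.9 (permutation p = 0.13). The longest run in each direction held 6 models, within the permuted maxima of 7 and 8. The longest falling run, on scaffold Nitab4.5_0001540, went from a summed 135 ± 6.71 CPM in controls (SD, n = 7) to 42.7 ± 5.64 in auxin-free libraries (SD, n = 3), with log2 fold changes from -1.11 to -2.65, and 4 of its 6 models had whole counts. The longest rising run, on scaffold Nitab4.5_0000714, went from 0.0145% ± 0.0123 of TMM-scaled reads in controls (SD, n = 7) to 0.0723% ± 0.0189 in auxin-free libraries (SD, n = 3), with a wide spread among the controls.

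Adjacent changed models shared their direction slightly more often than permuted ones, in 53.7% of 7861 pairs against 50.1% (permutation p = 1e-04, the smallest that 10000 permutations give). The excess was 3.6 points for adjacent models, 1.97 for every second model, 1.17 at a distance of 5 and -1.21 at a distance of 10. A candidate explanation is reads shared between tandem copies. Among pairs whose lengths differ by over 20% the excess was 2.45 points over 6325 pairs (permutation p = 1e-04), and among such pairs with whole counts it was 2.62 points, but over 72 pairs (permutation p = 0.371), too few to decide. Regulation of neighbours as a unit is an untested alternative.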
